A study of Mus musculus with 2 samples.

How the data were processed

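The study measured total RNA of 2 pools of mouse embryonic forebrain, with 1 gene table and 1 transcript table per library. Per the labels' protocols, RNA over 200 nucleotides was used, 10 ng per library, with spike-ins. The labels call the material total RNA, while a manual linked among the protocols is of a cDNA kit (SMARTer Ultra Low) that primes from poly(A) tails; the priming used is not stated. Per the file headers and the notes deposited with the files, the genome was mm10 and the annotation GENCODE M4, and the values derive from alignments to the transcriptome; the aligner, the quantifier, their versions and the strand setting are not given in the sources used here. The expected counts deposited by the authors are estimated reads per gene or transcript and need not be whole, since reads that fit several transcripts are divided among them. The deposited TPM values scale these by effective length to a fixed sum over all features, spike-ins included, and the deposited FPKM values scale them per kilobase and library size; both come as maximum-likelihood estimates and as posterior means, of which the posterior mean FPKM was not used here. The deposited percent values give each transcript's share of its gene. The effective length equals the length minus 99 for transcripts longer than that, which affects short RNAs most.

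Expected counts summed to 38720511 and 35103430. Of 69691 entries, 43346 were mouse genes, 96 were spike-ins, 1 was the phiX control with 0 reads and 26248 were transfer RNA entries; the last were left out of all comparisons. Symbols were joined by identifier without version, for 42462 genes (98.0%); genes without one held 0.256 and 0.279% of TPM. Gene types, coordinates and transcript names come from GENCODE M21 on the same assembly, whose gene models differ from M4.

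Samples were grouped by the labels, which describe the replicates as separate pools. Lists, tests and alternatives were fixed before the data were examined: 36 gene lists, with the 4 highest members and the lowest measured member named; the genes of the ratio pairs; the 10 highest nuclear protein-coding genes other than ribosomal proteins and histones; the 8 largest log2 ratios in each direction among genes at a mean of 5 TPM and 100 summed reads; and isoform genes whose main transcript held under 60% (at most 8) or differed between libraries. Other names in the text were chosen after their values were seen, and so were 14 further lists (further choroid plexus, hypothalamic and thalamic genes, motile cilia, genes that fall or rise with age, 7SL, 7SK and RNase P RNAs, the Sox and nuclear factor I families, Eph, Robo and semaphorin receptors, tubulins, and the Reelin pathway). Ca9 of the hypoxia list had no match. Some genes that these rules name, and 1 ratio pair, are not reported here. List levels are medians over members of log2(TPM + 0.1), from the mean TPM of the 2 libraries. Differences of these are given with the SD of the differences in the single libraries. They can lie outside both library values where the middle member of a list differs. A gene counted as detected at 1 TPM in both libraries. For 0 reads the limit is 3 reads per library, converted to TPM. Confidence intervals are at 95% (Wilson for shares, exact binomial for ratios of reads).

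For the pools, expected counts were rounded to whole numbers, scaled by TMM factors in edgeR 4.0.16 (R 4.3.3) for genes with a summed count of 10 or more, and an intercept-only common dispersion was fitted. Log2 ratios were computed after adding 0.5 reads. A list's percentile comes from 10000 random lists, each member replaced by 1 of the 100 nearest genes on either side in mean expression. Alternatives used DESeq2 1.42.0, spike-in scaling, no count filter, CPM without length correction, posterior mean TPM, other pseudocounts and thresholds, and 1 library at a time; after seeing the data, removal of a trend on GC content (20 bins) and a background of protein-coding genes were added. Spike-in scaling shifted the median log2 ratio of all genes by 0.20. The steps were tested on simulated data with a true coefficient of variation of 0.1: without changed genes the estimate was 0.0992 over 18887 genes, and with 200 genes changed 2-fold it was 0.115 over 18897. In the latter simulation the changed genes' median log2 ratio was 0.99, and all 20 changed lists of 10 genes lay outside the 95% range. Of 100 lists drawn at random from all genes, changed ones included, 5 did. Without changed genes, 3 of 100 random lists and 3 of the 20 lists lay outside. Simulated genes varied independently, so these rates need not hold for lists whose genes vary together, or for shifts below 2-fold. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.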

Results

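Total RNA longer than 200 nucleotides was profiled by sequencing in the mouse forebrain at embryonic day 15.5, an age within the period of cortical neurogenesis. The strain was B6NCrl and the embryos were of mixed sex. There was 1 group with 2 biological replicates: replicate 1 came from a pool of 78 embryos and replicate 2 from a separate pool of 62. Each library started from 10 ng of RNA with added spike-in transcripts. The expected counts summed to 38720511 in replicate 1 and 35103430 in replicate 2. With 1 group there was no condition to contrast, so the results are a profile of the tissue, comparisons between lists of genes within it, and the agreement of the pools. Levels below are TPM, the relative abundance of a gene's transcripts in a library corrected for length, given as mean ± SD of the 2 libraries (n = 2), or as the value in replicate 1 and then replicate 2. With 2 libraries the smallest p a two-sided exact sign-flip test allows is 0.5, so no test was made and differences were set against the spread between the libraries. Intervals and detection limits cover counting error only.

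Tubulin, stathmin and actin-linked genes were among the most abundant coding messages. Tuba1a, an alpha-tubulin of young neurons (ENSMUSG00000072235.5; chromosome 15, 98949837 to 98953703, minus strand, in mm10 coordinates of the GENCODE M21 gene span), stood highest among nuclear protein-coding genes other than ribosomal proteins and histones, at 13749 ± 152 TPM. Stmn1, a microtubule-destabilising protein, followed at 6569.6 ± 50.7 TPM (chromosome 4, 134468320 to 134473843). The actin-linked genes Tmsb4x (6101 ± 4.73), Actb (6060.1 ± 205) and Tmsb10 (3764 ± 136) were also among the 10 highest. The remaining members were the imprinted gene Nnat (5801 ± 83.7), the ferritin chain Ftl1 (5174 ± 106), the globin Hba-a2 (4853 ± 242), Ubb (3796 ± 30.6) and the elongation factor Eef1a1 (3251 ± 37.6). In all, 14895 of 43346 genes reached 1 TPM in both libraries, 13020 of them protein-coding, which was 60.6% of the 21474 protein-coding genes measured. A level of 100 TPM or more in both libraries was seen for 1622 protein-coding genes, and 4152 had no read in either library. Tuba1a, Ftl1, Actb, Hba-a2 and Eef1a1 have close paralogs or pseudogenes, so their levels depend on how shared reads were divided.

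Regulators of the telencephalon, the anterior part of the forebrain, had a list median far above those of other brain regions. Lhx2, a regulator of cortical identity, stood at 83.7 ± 11.5 TPM (chromosome 2, 38339281 to 38369733), Nr2f1 at 65.2 ± 6.43 and the dorsal regulator Emx1 at 61.2 ± 5.65. The lowest of the 7 telencephalic members, Otx1, was at 8.42 ± 0.453. The diencephalic list was uneven, and some of its members exceeded telencephalic ones: Tcf7l2, expressed in thalamus, reached 78.0 and 107 TPM in the libraries, Lhx9 16.7 and 20.3 and Gbx2 7.79 and 12.6, while Nkx2-4 was at 0.630 and 0.260. None of the 12 midbrain and hindbrain regulators and none of the 15 posterior Hox genes reached 1 TPM in both libraries.

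The list medians of log2(TPM + 0.1) differed by 4.82 ± 0.38 between telencephalic and diencephalic regulators, a 28.2-fold difference from mean TPM. In the single libraries it was 5.19 and 5.73, because a different gene was the middle member of the diencephalic list; it was 3.47 as the mean over members and 4.03 without length correction. The difference was 8.91 ± 0.27 for midbrain and hindbrain regulators and 9.12 ± 0.32 for posterior Hox genes, each larger than the spread between the libraries (7.90 and 8.30 as the mean over members). Egr2 stood highest among midbrain and hindbrain regulators at 0.240 ± 0 TPM, then Tph2 at 0.270 and 0.0900, Atoh1 at 0.0200 and 0.210 and Hoxb2 at 0.0600 and 0.0600. En2 had 0 reads in both libraries, which allows up to 0.0373 TPM in replicate 1 at 3 reads. Among posterior Hox genes Hoxa9 (0.0700 TPM), Hoxb7 (0.0700), Hoxa10 (0.0300) and Hoxc5 (0.0300) rested on 1 or 2 reads in replicate 1 and 0 in replicate 2, and Hoxb8 had 0 reads in both (up to 0.0928 TPM in replicate 1). These differences depend on the pseudocount, because members near 0 set the lower medians. Nr2f1 overlaps an antisense gene at 30.1 TPM, and the strand used in counting is not given in the sources used here.

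**Figure D1:**
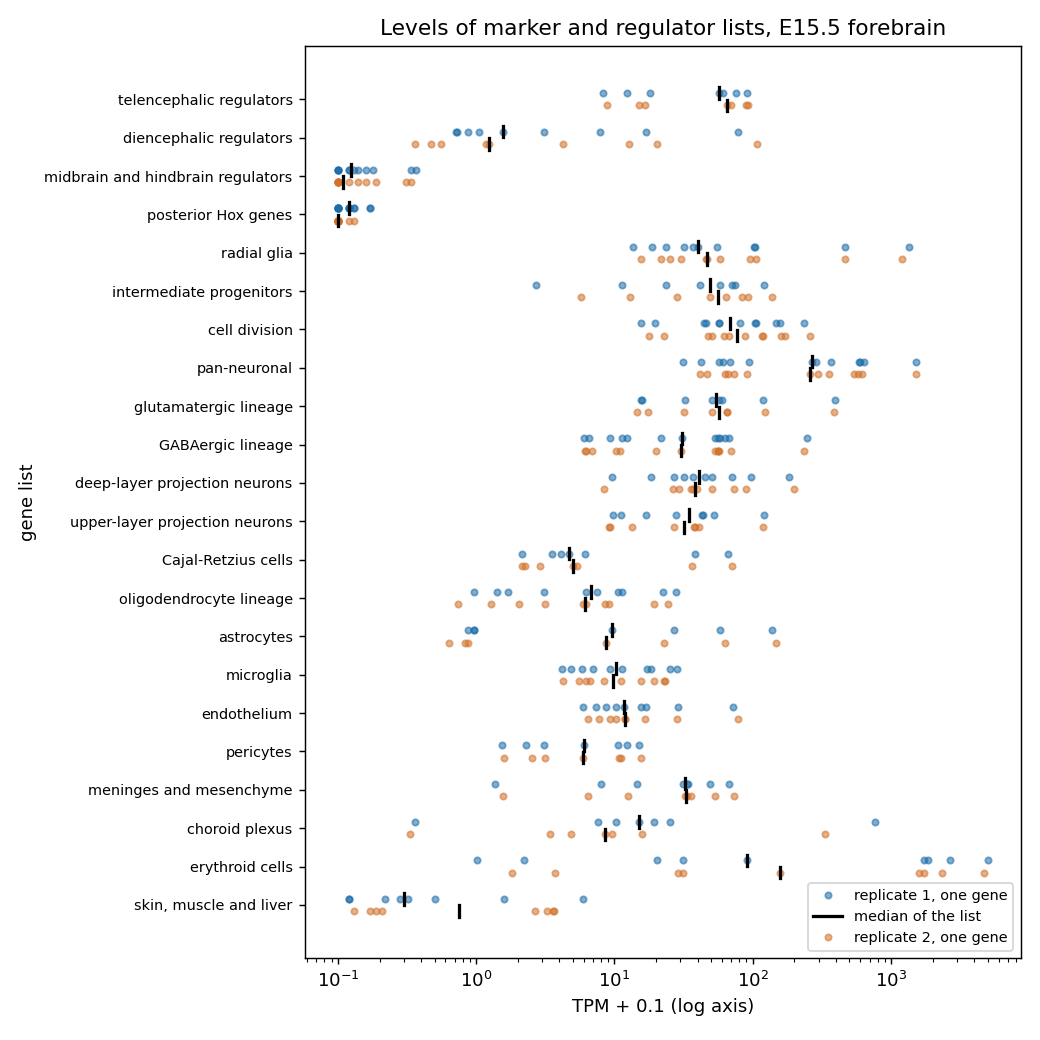
TPM + 0.1 on a log axis for each gene of 22 lists, with 1 point per gene for replicate 1 (blue) and replicate 2 (orange) and a black bar at the list median in each library. The medians of the telencephalic and pan-neuronal lists lie above those of the diencephalic, midbrain and hindbrain, and posterior Hox lists in both libraries; the pan-neuronal medians were 266 and 261 TPM.

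The median of the pan-neuronal list exceeded those of the progenitor and cell division lists, while single members overlapped. Tubb3, the neuronal beta-tubulin, stood at 1509 ± 3.27 TPM (chromosome 8, 123411424 to 123422015), Stmn2 at 626 ± 20.7, the growth cone protein Gap43 at 587 ± 13.2 and the microtubule-associated protein Mapt at 564 ± 29.0. All 13 pan-neuronal genes passed 10 TPM in both libraries, with Nefm lowest at 36.3 ± 7.05. Among genes of radial glia, the neural stem cells of the ventricular zone, Fabp7 was at 1274 ± 101 TPM, Vim at 466 ± 0.240, Hes5 at 104 ± 1.17 and Slc1a3 at 98.5 ± 4.36, with Hes1 lowest at 14.6 ± 1.35. Gadd45g (129 ± 12.8), Neurog2 (83.2 ± 12.4), Sstr2 (77.5 ± 9.23) and Btg2 (60.5 ± 4.21) led the intermediate progenitor list, and Neurog1 was lowest at 2.63 and 5.60 TPM. In the cell division list Ccnd2 was at 248 ± 19.5, Cdk1 at 159 ± 16.4, Pcna at 158 ± 1.06, Ccnb1 at 113 ± 9.29 and Mki67 at 16.5 ± 1.46.

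The log2 difference from the pan-neuronal median was -2.62 ± 0.18 for radial glia (6.13-fold), -2.33 ± 0.15 for intermediate progenitors (5.02-fold) and -1.86 ± 0.15 for cell division (3.64-fold), each beyond the spread between the libraries. Without length correction they were -2.12, -2.95 and -2.26. The mean over members gave smaller differences for radial glia (-1.47) and cell division (-1.38). These are ratios of transcript abundance and not of cell numbers. Nefl and Nefm overlap on opposite strands in the annotation, so their separate levels are uncertain.

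Both main neuronal lineages of the telencephalon were present, with the glutamatergic list above the GABAergic list. Neurod6, a transcription factor of cortical excitatory neurons, stood at 389 ± 5.54 TPM (chromosome 6, 55677822 to 55681263), Neurod2 at 119.9 ± 3.13, Neurod1 at 62.3 ± 3.13 and Emx1 at 61.2 ± 5.65, with Bhlhe22 lowest at 15.1 ± 0.933. On the GABAergic side Dlx1, a regulator of the ventral telencephalon, reached 239.6 ± 8.27 TPM, Dlx5 68.2 ± 1.70, and the GABA-synthesising enzymes Gad2 59.8 ± 4.86 and Gad1 57.3 ± 0.424, while the vesicular transporter Slc32a1 was lowest at 6.02 ± 0.184. All members of both lists passed 1 TPM in both libraries.

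The difference of the medians was log2 0.88 ± 0.08 (1.84-fold), beyond the spread between the libraries. That spread does not cover the choice of members, which ranged from 15.1 to 389 TPM in the glutamatergic list and from 6.02 to 240 TPM in the GABAergic list. The order of the lists therefore does not give that of the lineages. Among interneuron subtype genes, the peptides Sst (208 ± 6.33 TPM) and Npy (101 ± 5.88) were high, Calb2 was at 68.3 ± 3.33 and Nxph1 at 34.4 ± 1.53. Pvalb and Vip had 0 reads in both libraries, which allows Pvalb up to 0.148 and Vip up to 0.0898 TPM in replicate 1. All 11 striatal projection neuron genes passed 1 TPM in both libraries, led by Meis2 (134 ± 6.31), Foxp1 (87.7 ± 4.74), Isl1 (51.1 ± 4.42) and Tac1 (57.9 and 42.1 in the libraries), with the dopamine receptor Drd2 lowest at 3.09 ± 0.424. Dlx1 overlaps the antisense gene Dlx1as at 85.7 TPM.

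Genes of deep and upper cortical layers were expressed at similar levels. In the deep-layer list Sox5 stood at 189 ± 11.3 TPM, Bcl11b at 92.9 ± 5.01, Fezf2 at 71.7 ± 1.85, Tbr1 at 50.7 ± 0.346 and Zfpm2 lowest at 8.88 ± 0.757. In the upper-layer list Cux1 was at 119 ± 1.57, Pou3f3 at 41.9 ± 1.84, Pou3f2 at 40.7 ± 4.32 and Unc5d lowest at 9.28 ± 0.431. The deep-layer median was above the upper-layer median by log2 0.25 ± 0.02 (1.19-fold). The direction turned without length correction, where the difference was -0.33, so no order of the lists is given.

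Glial, vascular, immune and other non-neural genes, and those of Cajal-Retzius neurons, had list medians below the pan-neuronal list, while single members, such as the adult globins, the choroid plexus gene Ttr and the astrocyte gene Aldoc, were abundant. This held for all 10 lists. The adult alpha-globin Hba-a2 was at 4853 ± 242 TPM, the beta-globin Hbb-bs at 2520.1 ± 241, Hba-a1 at 1786 ± 88.6, Hbb-bt at 1664 ± 96.5 and the embryonic globin Hbb-bh1 lowest at 0.910 and 1.72. The erythroid list differed from the pan-neuronal list by log2 -1.09 ± 0.60 (-3.47 without length correction and -0.48 as the mean over members), with medians of 90.02 and 158 TPM in the libraries. Ttr, the thyroid hormone carrier secreted by the choroid plexus, stood at 761 and 331 TPM in the libraries, Folr1 at 25.2 and 15.6, Kcne2 at 19.3 and 9.53, Otx2 at 14.9 and 8.42 and Kl at 0.260 and 0.230, for a list difference of -4.49 ± 0.56 (-4.15 and -4.94 in the libraries and -5.28 without length correction).

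In the oligodendrocyte list (difference -5.35 ± 0.09) Olig1 was at 26.1 ± 2.33 TPM, Cnp at 20.8 ± 2.09, the myelin gene Mbp at 10.1 ± 1.58 and Mag lowest at 0.750 ± 0.156. In the astrocyte list (-4.85 ± 0.07) Aldoc reached 142 ± 5.71, Gja1 60.5 ± 3.39, Aldh1l1 24.9 ± 3.05 and Slc1a2 9.04 ± 0.587. The water channel Aqp4 was at 0.705 ± 0.233, and 4 of the 7 members passed 1 TPM in both libraries. In libraries of whole tissue, the level of a gene from any of these lists does not show which cells expressed it. Microglial genes (-4.73 ± 0.04) included the complement genes C1qb (24.3 ± 1.44), C1qa (18.8 ± 0.721) and C1qc (16.4 ± 1.15), with Tmem119 at 4.12 ± 0.0778. Endothelial genes (-4.58 ± 0.04, with -4.51 and -4.45 in the libraries) were led by the tight junction gene Cldn5 (75.1 ± 4.40), Esam (28.5 ± 0.226), Kdr (16.6 ± 0.134) and Slco1c1 (13.6 ± 2.57), with Tek at 6.04 ± 0.361. In the pericyte list (-5.46 ± 0.00) Rgs5 was at 15.2 ± 0.325, Kcnj8 at 11.6 ± 0.827, Pdgfrb at 10.6 ± 0.177, Acta2 at 5.92 ± 0.0778 and Anpep at 1.47 ± 0.0495. Collagen and other mesenchymal genes (-2.99 ± 0.03, with -3.04 and -3.00 in the libraries) included Col3a1 at 69.9 ± 3.97, Igf2 at 51.2 ± 3.05, Dcn at 33.4 ± 3.29, Col1a1 at 33.4 ± 0.304 and Foxc1 at 1.36 ± 0.134. Cajal-Retzius genes (-5.77 ± 0.09) were led by Calb2, then Reln at 37.1 ± 1.36, Lhx5 at 5.64 ± 0.488, Trp73 at 4.75 ± 0.226 and Ebf2 at 2.11 ± 0.0849. Of the 8 skin, muscle and liver genes (-8.59 ± 0.96; -9.80 and -8.44 in the libraries), Acta1 was at 5.83 and 3.17 TPM, Apoa2 at 1.5 and 3.49, Afp at 0.0200 and 3.56, Alb at 0.0200 and 2.58 and Myog at 0.180 and 0.0300. Cnp and Lhx5 overlap antisense genes at 250.0 and 5.13 TPM. Hba-a1 and Hba-a2, and Hbb-bs and Hbb-bt, are near-identical pairs whose separate levels are uncertain. Without length correction the differences were -3.35 for astrocytes, -5.41 for microglia and -3.61 for mesenchymal genes, and as the mean over members -3.71 for endothelium, -4.15 for microglia and -4.61 for Cajal-Retzius genes. With a pseudocount of 1 the skin, muscle and liver list gave -7.30.

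Receptor subunits and transporters of the same family differed widely in level. The NMDA receptor subunit Grin2b, which predominates in the embryonic brain, was at 38.5 ± 0.177 TPM and exceeded Grin2a, at 1.52 ± 0.113, by log2 4.57 ± 0.11 (23.8-fold). Without length correction this log2 ratio was 6.20, and Grin2a had 59 and 51 reads. As gene totals, the AMPA receptor subunit Gria2 exceeded Gria1 (173 ± 13.7 against 47.7 ± 3.31, log2 1.86 ± 0.01). The Gria2 total includes transcripts not annotated as coding, such as the retained-intron Gria2-206 at 63.43 and 57.26 TPM in the libraries. The leading coding transcripts were closer, with Gria2-202 at 67.82 and 56.93 TPM and Gria1-201 at 42.44 and 36.01 TPM. The log2 ratio of the totals is therefore not that of the coding messages, which was not computed. Of the chloride transporters, Slc12a2, which brings chloride into the cell, was at 5.30 ± 0.509 and Slc12a5, which extrudes it, at 10.1 ± 0.00707, a log2 ratio of -0.92 ± 0.14.

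The vesicular glutamate transporter Slc17a6 (31.9 ± 0.198 TPM) exceeded Slc17a7 (16.4 ± 1.51) by log2 0.96 ± 0.14. The neuronal splicing regulator Ptbp2 (194 ± 9.13) exceeded Ptbp1 (92.2 ± 6.89) by log2 1.07 ± 0.18, and Grin1 (16.9 ± 1.43) stood below Grin2b by a log2 ratio of -1.19 ± 0.13. Without length correction the log2 ratios were 1.59 (Gria2 over Gria1), -0.49 (Slc12a2 over Slc12a5), 1.53 (Slc17a6 over Slc17a7), 1.40 (Ptbp2 over Ptbp1) and -1.87 (Grin1 over Grin2b). In all 6 pairs the ratio was larger than the spread between the libraries. Across the 15 glutamate and GABA receptor genes, 13 passed 1 TPM in both libraries, among them Gria2, Gria1 and the GABA receptor subunit Gabra2 (44.1 ± 5.48), with Grin2c lowest at 0.185 ± 0.00707. Ptbp1 overlaps the antisense gene Plppr3 at 337 TPM.

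**Figure D2:**
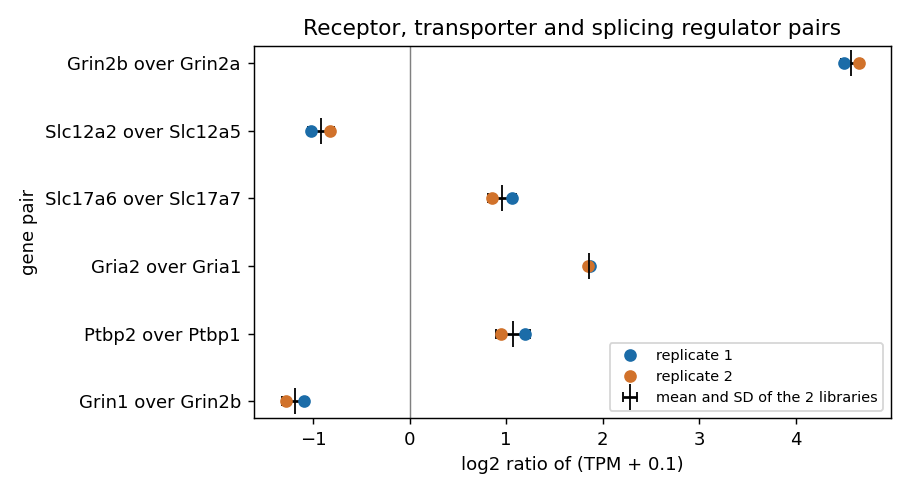
Log2 ratio of (TPM + 0.1) for 6 gene pairs in replicate 1 (blue) and replicate 2 (orange), with the mean and SD of the 2 libraries in black. Both libraries lie on the same side of 0 for every pair, from 4.57 for Grin2b over Grin2a to -1.19 for Grin1 over Grin2b.

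All 14 imprinted genes passed 1 TPM in both libraries. Nnat stood at 5801 ± 83.7 TPM, Ndn at 864 ± 101, the noncoding Meg3 at 813 ± 40.6 and Snrpn at 401 ± 7.11, with Peg10 lowest at 6.51 ± 0.615. Transcripts of both sexes were present: the Y-linked Eif2s3y was at 37.1 ± 4.29, Ddx3y at 13.9 ± 2.67 and Uty at 7.40 ± 1.03, and the X-inactivation RNA Xist was at 26.5 ± 0.184, with its overlapping antisense partner Tsix at 12.7 ± 1.30, a pair whose separate levels are uncertain. The immediate early genes Jun (68.6 ± 2.94), Dusp1 (39.9 ± 2.07), Ier2 (24.6 ± 4.26) and Junb (6.12 ± 0.0495) led their list, and Fosb was at 0.0550 ± 0.00707 TPM. Of the hypoxia and glycolysis genes, Ldha was at 626 ± 14.6, Pgk1 at 211 ± 10.5, the glucose transporter Slc2a1 at 77.8 ± 1.37, Bnip3 at 63.4 ± 2.66 and Vegfa lowest at 2.67 ± 0.354. Housekeeping genes ranged from Tbp at 57.3 ± 1.14 to Actb, with Ppia at 3063 ± 6.38 and Gapdh at 1221 ± 15.2. Dusp1, Junb and Tbp overlap antisense genes at 68.8, 1197 and 51.5 TPM, and Ppia, Gapdh, Ldha and Pgk1 have pseudogenes.

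The libraries held both polyadenylated messages and RNAs without a poly(A) tail. The labels leave open how cDNA was primed, so these shares need not be those in the tissue. Mitochondrial mRNAs took 2.37 ± 0.0707% of TPM, led by mt-Atp6 (6109.6 ± 214 TPM), mt-Atp8 (5600.3 ± 102), mt-Cytb (2517 ± 12.2) and mt-Co1 (2258 ± 36.7), with mt-Nd4l lowest at 54.3 ± 4.21. Cytosolic ribosomal proteins took 4.12 ± 0.138%, led by Rpl41 (2011 ± 98.2), Rps19 (1278 ± 73.3), Rpl32 (1109.8 ± 4.58) and Rps29 (1057 ± 69.8), and Rpl10l had 0 reads in both libraries, which allows up to 0.139 TPM in replicate 1. Replication-dependent histones took 0.310 ± 0.0382%, led by Hist1h2ap (1800.0 ± 304), Hist3h2ba (302 ± 9.96), Hist1h4d (239 ± 25.2) and Hist3h2a (132 ± 2.33); Hist1h4m had 0 reads in both. The list of RNAs without a poly(A) tail took 3.32 ± 0.643%, nearly all of it the signal recognition particle RNA of Rn7s1 and Rn7s2, which are near-identical copies and summed to 28098 and 37110 TPM. Rn7sk was at 446 ± 32.1, the RNase P RNA Rpph1 at 152 ± 13.0 and the telomerase RNA Terc lowest at 0.530 and 0.140.

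Spike-ins took 5.55 ± 0.584% of TPM. As a share of expected counts, with 95% Wilson intervals in parentheses, mitochondrial mRNAs made up 0.994% (0.991 to 0.998%) in replicate 1 and 0.976% (0.973 to 0.979%) in replicate 2, histones 0.0845% (0.0836 to 0.0855%) and 0.0984% (0.0974 to 0.0995%), and RNAs without a poly(A) tail 0.349% (0.347 to 0.351%) and 0.466% (0.464 to 0.468%). Ribosomal proteins made up 1.47% (1.47 to 1.47%) and 1.55% (1.54 to 1.55%) of counts and spike-ins 2.44% (2.44 to 2.45%) and 2.13% (2.12 to 2.13%). The shares differed between the libraries by more than these intervals for each class. Histone genes, mitochondrial genes and ribosomal protein genes share reads with close copies or pseudogenes.

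The pools gave closely similar profiles. Across 19165 genes with a summed count of 10 or more, Pearson's r of log2 CPM (counts scaled to library size) was 0.985 and Spearman's rho 0.994; these are across genes, which are not independent replicates. The biological coefficient of variation from edgeR's common dispersion was 0.0638 on 1 residual degree of freedom. DESeq2's median dispersion gave 0.0001, its lower limit. The chi-square of the counts against sampling noise was 5.82 per degree of freedom, so the pools differed by more than counting error. Each library is a pool of embryos, so these values do not give the variation between single embryos. Among 11215 genes at 5 TPM and 100 reads or more, 36 differed by over 2-fold, of which 22 were protein-coding.

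The largest single-gene differences between the pools were mostly in pseudogenes and gene copies, with a few exceptions. The hypothalamic hormone gene Avp was at 40.9 and 4.45 TPM (8.92-fold higher in replicate 1), and the cardiac actin Actc1, which has close paralogs, at 1.96 and 18.4 (9.44-fold higher in replicate 2). Adnp, a chromatin-associated factor, was at 3.44 and 10.8 and Eid2 at 4.46 and 13.8, while the cilia gene Cfap126 was at 8.57 and 3.35, Gm14434 at 15.8 and 4.36 and the histone Hist1h2ai at 20.0 and 7.21. The pseudogenes Rpl7a-ps11 (0 and 17.9), Gm4294 (18.0 and 0), Rpl30-ps9 (25.4 and 0), Gm12191 (1.44 and 35.2), Gm8226 (14.2 and 2.57), Rpl21-ps15 (3.67 and 15.5) and Rps15a-ps7 (4.19 and 13.2) share reads with parent genes and are uncertain. So are ENSMUSG00000090407.1 (26.8 and 0) and ENSMUSG00000090234.1 (4.22 and 31.0), which have no match in the annotation used here.

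Choroid plexus genes were higher in replicate 1. The list median of the log2 ratio of replicate 2 over replicate 1, relative to all genes, was -1.0 (2.00-fold), with all 7 members below 0, and Ttr was 2.27-fold, Clic6 2.21-fold and Aqp1 2.10-fold higher. Progenitor genes were slightly higher in replicate 2: 0.27 for intermediate progenitors (8 of 8 members), 0.17 for cell division (12 of 12) and 0.09 for radial glia (8 of 11). The telencephalic list stood at 0.19. These medians lay outside the central 95% of 10000 random lists matched on mean expression, as did 16 of 34 lists in all. With 1 pool on each side this describes the libraries and tests no difference between conditions.

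The other lists outside that range toward replicate 2 were RNAs without a poly(A) tail (0.41), replication-dependent histones (0.14), sex-linked genes (0.21), cytosolic ribosomal proteins (0.08), the skin, muscle and liver list (0.61) and diencephalic regulators (0.20). Toward replicate 1 were striatal projection neurons (-0.17), the oligodendrocyte lineage (-0.18), glutamate and GABA receptors (-0.10), erythroid cells (-0.08) and mitochondrial mRNAs (-0.04). Only members with a summed count of 10 or more were tested. Among them, both directions occurred in each of these lists except the RNAs without a poly(A) tail (5 of 8 members tested). Lower in replicate 2 were 8 of 11 striatal, 8 of 10 oligodendrocyte, 11 of 15 receptor, 5 of 9 erythroid and 8 of 13 mitochondrial members. Higher in replicate 2 were 38 of 59 histone, 5 of 6 sex-linked and 74 of 85 ribosomal protein members. So were 5 of 9 diencephalic members and only 3 of 6 skin, muscle and liver members. The median TPM of the striatal (29.4 and 36.8) and erythroid lists rose and that of the diencephalic list (1.47 and 1.13) fell in replicate 2, against their median ratios. The diencephalic median lay within the range with TPM or without a count filter (0.17 and 0.19), and the skin, muscle and liver median turned to -0.48 without that filter. In the last list, Alb had 1 and 108 reads, a ratio of 79.8 (95% counting interval 20.9 to 4748), and Afp 1 and 152, a ratio of 112 (29.6 to 6665), while Acta1 was 1.81-fold higher in replicate 1. Within the range were pan-neuronal (0.01), deep-layer projection neurons (0.05), upper-layer projection neurons (-0.07), glutamatergic lineage (0.05), GABAergic lineage (-0.03), interneuron subtypes (0.08), Cajal-Retzius cells (0.05), astrocytes (-0.06), microglia (-0.09), endothelium (0.02), pericytes (0.06), meninges and mesenchyme (-0.01), midbrain and hindbrain regulators (-0.38), chloride transporters (0.03), imprinted genes (0.04), immediate early genes (0.11), hypoxia and glycolysis (0.08) and housekeeping (0.06). Of these, the upper-layer list (-0.14) and the hypoxia and glycolysis list (0.12) came to lie outside the range with TPM, and microglia (-0.11) with a GC trend removed. Posterior Hox genes had too few reads, and the isoform gene list was used for transcripts alone. mt-Co2 (1235 and 796 TPM) shares reads with mitochondrial pseudogenes, and the mitochondrial list moved to 0.00 after a trend on GC content was removed.

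**Figure D3:**
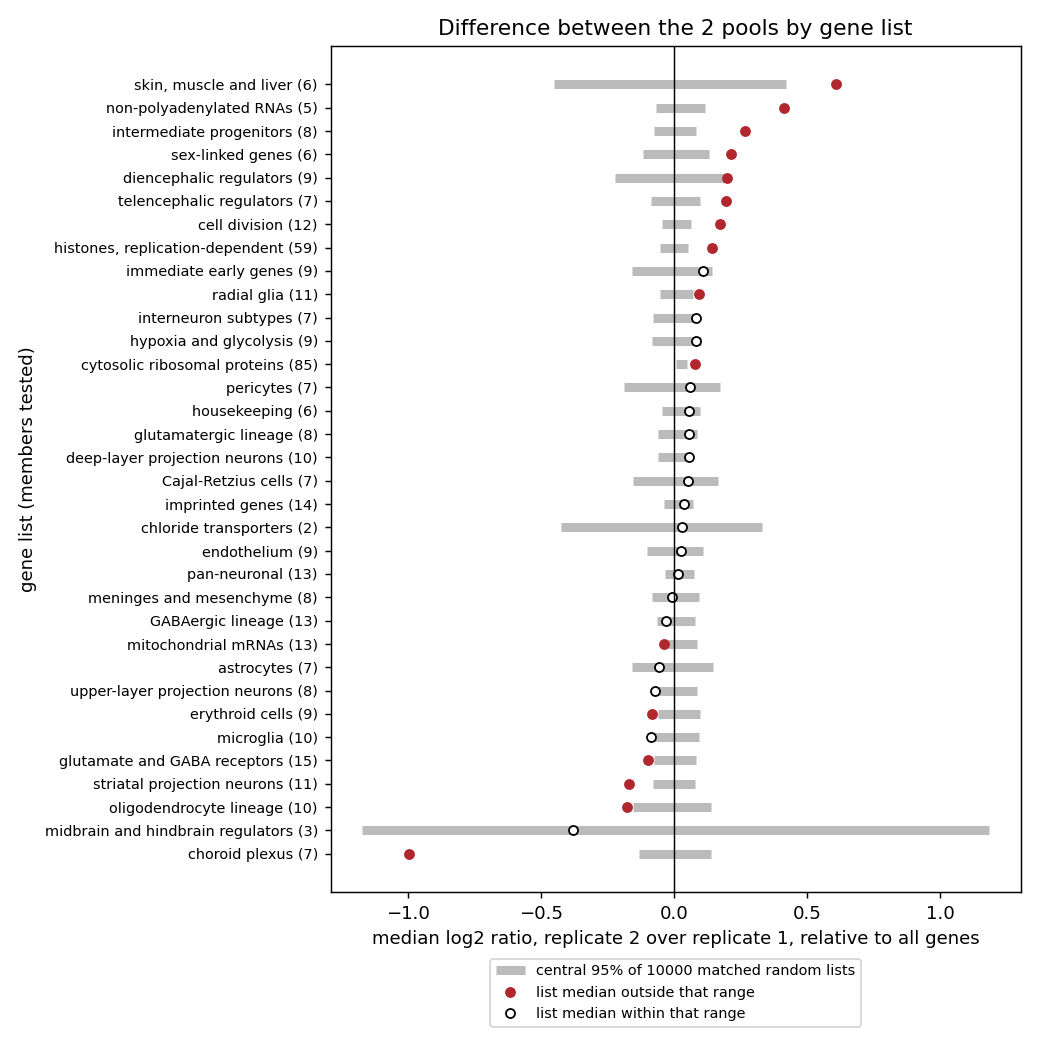
Median log2 ratio of replicate 2 over replicate 1 relative to all genes for 34 lists, with the number of members tested in parentheses; grey bars span the central 95% of 10000 random lists matched on mean expression, and filled points lie outside them. The choroid plexus list is farthest to the left at -1.0 and the skin, muscle and liver list farthest to the right at 0.61. In the latter list, 3 of 6 members tested were higher in replicate 2 and 3 lower.

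Many genes with several annotated transcripts used more than 1 of them. Of 10020 genes at 1 TPM or more in both libraries with 2 or more transcripts, 6345 (63.3%) had 2 or more transcripts each holding 10% or more of the gene in both libraries. At a cut of 20% the count was 3599 of 10020. The main transcript was the same in both libraries for 9220 genes (92.0%), and held a median share of 68.7 and 68.4%. Cdc42, a small GTPase with 2 alternative last exons, divided into Cdc42-202 at 56.1 ± 1.77% and Cdc42-201 at 43.9 ± 1.77%. Mapt was led by Mapt-205 (47.3 ± 0.366%) and Mapt-204 (34.3 ± 1.17%), Map2 by Map2-201 (38.8 ± 1.98%), and the migration gene Dcx by Dcx-203 (40.4 ± 1.38%) and Dcx-201 (38.5 ± 0.168%).

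Bcl11a was led by Bcl11a-204 (48.4 ± 0.0724%), Dclk1 by Dclk1-201 (47.5 ± 0.694%) and Dclk1-203 (44.5 ± 1.17%), and Dab1 by Dab1-207 (39.8 ± 2.60%), annotated for nonsense-mediated decay. Of 28 genes tested from the isoform list, the main transcript held under 60% in both libraries for 19 and 90% or more for 1, and it differed between the libraries for 4. For Gria2 the coding Gria2-202 held 37.1 and 34.8% and the retained-intron Gria2-206 34.7 and 35%. For Dlg4, Dlg4-201 held 25.3 and 33.1% and Dlg4-208 23.5 and 36.5%, and for Grin1, Grin1-205 held 25.3 and 19.4% and Grin1-206 13.2 and 27.2%. Since the order of the leading transcripts in these genes depended on the library, none is ranked first. Transcript shares are model estimates from reads that several transcripts share.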

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

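The tests of the share of blood and of priming from tails alone were chosen after the result was seen. Of 26248 transfer RNA entries, which enter no comparison, 9 had any read in replicate 1 and 9 in replicate 2. Those above the limit of 3 reads that a count of 0 allows, which flagged them, had 6 and 4.67 reads in replicate 1 and 4 in replicate 2. Among so many entries, these few reads are no evidence that transfer RNA was measured.

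Choroid plexus and diencephalic genes differed between the pools. For the choroid plexus list, the median was still -0.99 after the GC trend was removed, which argues against GC content. Of 14 further choroid plexus genes, 7 passed 1 TPM in both libraries, led by Igfbp2 (281 ± 4.81 TPM) and Slc31a1 (33.0 ± 0.820). The median ratio was -0.48 over the 13 with a summed count of 10 or more, of which 11 were lower and 2 higher in replicate 2. It lay between the bounds of -0.5 and -0.3 set before the test, so a larger share of choroid plexus in replicate 1 remains open. Motile cilia genes, also a list chosen after seeing the data, moved the same way (median -0.76, all 10 members below 0), and were not used to decide this. Further hypothalamic genes, led by Fezf1 (11.2 and 6.04 TPM), had a median of -0.49 (15 of 17 members lower in replicate 2). Further thalamic genes had a median of 0.16 (7 of 10 higher), although the most abundant, Zic4 (45.3 and 38.0), which overlaps the antisense gene Zic1 at 8.05 TPM, was lower. Both medians lay beyond 95% of random lists on the sides predicted. The further choroid plexus, hypothalamic and thalamic lists were chosen after seeing the data of these same libraries. They therefore give no independent test of whether the dissections held different shares of subdivisions of the diencephalon. The labels name no anatomical difference between the pools.

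Embryonic and adult globins moved apart between the pools. The embryonic globins Hbb-y, Hba-x and Hbb-bh1 were higher in replicate 2 and the 4 adult globins lower, a difference of medians of 0.95, which argues against a different share of blood as the whole cause. Slightly younger embryos in replicate 2 were considered as another explanation. Genes that fall with age had a median of 0.13, outside the 95% range. Both lists of age-related genes were chosen after seeing the data of these same libraries, so they give no independent test of age. Genes that rise with age had a median of -0.020, within the range and with members on both sides, so this explanation cannot be told apart from others. The labels give 1 age for both pools, so a difference in age was not part of the design.

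Replication-dependent histones, most of whose messages lack a poly(A) tail, were detected at intermediate levels. Their median was 3.76 TPM, between the bounds set before the test, which were 1 TPM and the median of the cell division list, so priming from poly(A) tails cannot be told apart from other priming by this value. The median of the 7SL, 7SK and RNase P RNAs was 7236 TPM in the lower library. It is a midpoint of 4 entries, which include the near-identical 7SL copies Rn7s1 and Rn7s2 and range from 152 to 16302 TPM in mean. These levels show that RNAs without a tail were captured. The bound for this test was set after they were seen, so the test does not decide how cDNA was primed. The labels call the material total RNA and also link the manual of a cDNA kit that primes from poly(A) tails, so the priming used is not known. No biological explanation was tested for the histone levels.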

How the results depend on the processing

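The alternatives with the GC trend removed and with protein-coding genes alone were chosen after seeing the data. Directions of the list comparisons and of all 6 gene pairs held under each alternative run, except deep-layer minus upper-layer, which was -0.33 without length correction. The cause was not tested for any change below. Without length correction, telencephalic regulators minus diencephalic gave 4.03 and minus midbrain and hindbrain 8.61; against pan-neuronal genes, radial glia gave -2.12, intermediate progenitors -2.95 and cell division -2.26; glutamatergic minus GABAergic gave 0.72. The pairs gave 6.20 (Grin2b over Grin2a), -0.49 (Slc12a2 over Slc12a5), 1.53 (Slc17a6 over Slc17a7), 1.59 (Gria2 over Gria1), 1.40 (Ptbp2 over Ptbp1) and -1.87 (Grin1 over Grin2b). With a pseudocount of 1 the regional differences were 4.34, 5.92 and 5.94 (diencephalic, midbrain and hindbrain, Hox), Grin2b over Grin2a 3.97 and Gria2 over Gria1 1.84; with 0.01 they were 10.70 (midbrain and hindbrain) and 11.58 (Hox). Keeping members at 0.1 TPM or more gave 7.77 for midbrain and hindbrain. Posterior mean TPM gave 8.34 (midbrain and hindbrain), 8.19 (Hox), 0.21 (deep minus upper) and 1.83 (Gria2 over Gria1). The mean over members gave 3.47, 7.90 and 8.30 for the regional lists, -1.47 for radial glia, -1.38 for cell division, 1.00 for glutamatergic minus GABAergic and 0.61 for deep minus upper. With 1 library left out the ranges were 5.19 to 5.73 (diencephalic), 8.84 to 9.22 (midbrain and hindbrain) and 0.24 to 0.26 (deep minus upper).

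As a percent of expected counts, mitochondrial mRNAs were 0.985, ribosomal proteins 1.51, histones 0.0915, RNAs without a poly(A) tail 0.408 and spike-ins 2.28; posterior mean TPM gave 2.54 for mitochondrial mRNAs. The count of genes with several transcripts was 3599 of 10020 at 20% of the gene, no longer most of them. DESeq2's median dispersion gave a coefficient of variation of 0.0001, its lower limit (a change beyond 1.5 times, or beyond 0.01 in a correlation, counted as moved, since no spread was available), and Spearman's rho was 0.983 without a count filter. Between the pools, the skin, muscle and liver list turned to -0.48 without a count filter. Mitochondrial mRNAs turned to 0.0019 with the GC trend removed. Of the other list values from settings that can change them, 128 kept their place inside or outside the range. Another 3 came to lie outside it and 2 inside. Some values that stayed inside it changed sign, such as Cajal-Retzius cells (0.05 to -0.06) and midbrain and hindbrain regulators (-0.38 to 0.02) with TPM. DESeq2 and spike-in scaling apply 1 factor to all genes and cannot change these values, so they are not counted. Of the values for the 10 lists of glia, non-neural cells and Cajal-Retzius neurons, 33 moved by more than the spread and none changed sign; the erythroid list moved to -3.47 without length correction and -0.48 as the mean over members. The other ranges over all settings were -5.42 to -4.97 (oligodendrocyte lineage), -4.90 to -3.35 (astrocytes), -5.41 to -4.15 (microglia), -4.59 to -3.71 (endothelium), -5.48 to -5.00 (pericytes), -3.61 to -2.95 (meninges and mesenchyme), -5.28 to -4.02 (choroid plexus), -9.80 to -7.30 (skin, muscle and liver) and -5.83 to -4.61 (Cajal-Retzius cells). The count of detected genes, 14895 at 1 TPM, was 19889 at 0.1 TPM and 11118 at 5 TPM, each within 1.5 times of it. Leaving out a library gives no value for the agreement of the pools or their difference. No paired analysis was possible because there was 1 group. Depth limits genes with few reads, such as the Hox genes.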

Other observations

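The lists and the group of 8 genes in this part were chosen after seeing the data. Families of neuronal differentiation and wiring genes ranged widely in level. Among Sox factors, Sox11 stood at 873 ± 4.19 TPM, Sox4 at 286 ± 11.1 (with an antisense gene at 107) and Sox9 at 56.7 ± 2.09, and 16 of 19 passed 1 TPM in both libraries, with Sox15 lowest at 0.0600 and 0.120. The nuclear factor I genes Nfix (353 ± 17.7), Nfib (234 ± 0.283), Nfia (82.6 ± 1.20) and Nfic (20.6 ± 2.65) all passed 10 TPM. Of the axon guidance receptors, Epha5 (128 ± 5.52), Epha4 (77.7 ± 1.22), Epha3 (58.4 ± 4.09) and Epha7 (48.9 ± 1.01) led 14 Eph receptors. Robo2 (84.3 ± 5.40) and Robo1 (37.6 ± 1.88) exceeded Robo3 (1.58 and 2.56) and Robo4 (2.67 and 3.39). Plxnb2 (91.1 ± 1.70), Nrp1 (67.7 ± 0.672) and Plxna2 (62.2 ± 3.39) led the semaphorin receptors.

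All 8 genes of the Reelin pathway and radial migration passed 10 TPM in both libraries, among them Dcx (292 ± 4.60), Dab1 (142 and 124), Cdk5r1 (99.5 and 86.5), Lrp8 (73.9 ± 4.10) and Vldlr (30.2 ± 2.26). Among tubulins, Tubb5 (1596 ± 0.969) stood second to Tuba1a, and Tubb2a (1312 ± 87.5) followed Tubb3. The noncoding RNA Malat1 was at 6031 ± 450.4 TPM. Between the pools, the medians were 0.08 for Sox factors, 0.05 for nuclear factor I, 0.17 for Robo receptors and -0.00 for tubulins, within the central 95% of random lists, and 0.09 for Eph receptors, 0.10 for semaphorin receptors and -0.09 for the Reelin list, outside it.

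Motile cilia genes were lower in replicate 2, with a median of -0.76 and all 10 members below 0; Tekt1 was at 9.03 and 5.16 TPM and Rsph1 at 5.66 and 3.36. A group of 8 genes of varied function was higher in replicate 2: Akt1 (65.6 and 122 TPM), Cdk2ap1 (70.8 and 159.8), Gna12 (21.9 and 54.1), Selenon (9.80 and 22.7), Dvl1 (8.77 and 19.1), Sppl3 (14.5 and 24.9), Adnp and Eid2. Their median log2 ratio was 1.24 and 1.22 after the GC trend was removed. Their median GC content was 57.6% against 50.5% over 10563 protein-coding genes. The group was picked by hand and is not the top of the ranking. Protein-coding genes left out of it, with larger ratios than Sppl3, had a GC content from 38.1% (Gm14419) to 61.2% (BC037034). The GC difference therefore depends on the choice of genes.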
